A study of Mus musculus with 25 samples.

How the data were processed

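Gene expression was measured by RNA sequencing in a pair of mouse experiments, each deposited as a table of estimated counts per Ensembl gene that the authors had not scaled to a common total. The first table held 16 libraries from hypothalami of mice that carried a tamoxifen-inducible Cre recombinase under the Slco1c1 promoter and a Cre-dependent GFP-tagged ribosomal protein L10a (bacTRAP, in which tagged ribosomes are precipitated with an antibody against GFP and the bound RNA is sequenced). Mice were 12 weeks old, were studied 3 weeks after tamoxifen and had been fed a control diet (CD) or a high-fat diet (HFD) for 3 days. Each diet had 4 pools, each of 4 mice (2 female and 2 male), and each replicate number had a library of the whole lysate (INPUT) and a library of the precipitated RNA (IP). The second table held 9 libraries of cEND cells, a mouse brain endothelial line, with vehicle (DMSO) or WZB117, an inhibitor of the glucose transporter Glut1, at 0.5 or 10 µM. Each treatment was run once at passages 12, 14 and 18, so that the replicates of the cEND groups are passages of 1 line and not separate animals. The treatment time, the program that estimated the counts and the annotation release were not given in the sources used here. The labels name genome build GRCm38, and coordinates in the text were taken from GENCODE release M21 by Ensembl identifier.

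The bacTRAP table listed 45706 genes, of which 45143 had a symbol in the annotation and 15491 had 0 in every library, and the cEND table listed 44674, 44118 and 18647 in the same order. Of the values, 17.3 percent in the bacTRAP table and 19.8 percent in the cEND table were not whole numbers, and estimated counts were rounded before fitting. Total counts per library, given in M (1e6 counts), ran from 27.9 to 42.8 M in the bacTRAP table, with 20647 to 23458 genes detected, and from 27.3 to 41.3 M in the cEND table, with 20022 to 20748 genes detected. No pair of libraries of a group held the same counts, the lowest chi-square per degree of freedom between any pair being 9.08. Errors are given as the spread between libraries and not as counting error. No column of either table was left out.

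Counts were normalised with TMM factors and fitted with the quasi-likelihood model of edgeR 4.0.16 (robust, filterByExpr for low counts) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes of a comparison, an adjusted p threshold of 0.05 and no threshold on the fold change. All p-values are from 2-sided tests. IP was compared with INPUT in the 16 bacTRAP libraries. HFD was compared with CD in the 8 IP libraries and in the 8 INPUT libraries apart, and the difference of both diet effects was tested as an interaction in the 16 libraries. The 3 comparisons among the cEND groups used 1 fit of the 9 libraries. CPM (counts scaled to a total of 1e6 per library) used TMM factors of the libraries of the comparison, so that a gene's CPM differs slightly between comparisons, and means are given with SD and fold changes with SE. In total 38 gene lists were tested per comparison with camera (limma 3.58.1, preset inter-gene correlation of 0.01, adjusted over the lists). Lists with fewer than 3 measured members in cEND cells could not be tested there.

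The lists held genes of Notch receptors, ligands and processing, Notch targets, glucose transport and glycolysis, the blood-brain barrier, insulin signalling, hypoxia, VEGF and angiogenesis, endothelial activation and inflammation, interferon response, and extracellular matrix and TGF-beta. Others covered Wnt and beta-catenin, the unfolded protein response, the amino acid and integrated stress response, NRF2 targets, p53 targets, heat shock, immediate early genes, glucocorticoid response, the circadian clock and the cell cycle. Metabolic lists covered cholesterol synthesis, fatty acid synthesis, fatty acid uptake and oxidation, nuclear oxidative phosphorylation, the mitochondrially encoded genes and ribosomal proteins. Cell-type lists covered pan-endothelial, neuronal, astrocyte, tanycyte and ependymal, choroid plexus, microglia and macrophage, oligodendrocyte, pericyte and smooth muscle, fibroblast, erythroid, anterior pituitary and hypothalamic neuropeptide genes.

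Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. By that rule up to 10 genes per direction were named that passed the adjusted p, had the largest change, an average log2 CPM of at least 1, no overlap between the libraries of the compared groups and a symbol that was not a placeholder. Where fewer than 5 genes passed, the 5 of smallest p were named as values. A fixed set of genes of Notch signalling, glucose transport, endothelium and insulin signalling was always reported, as were up to 4 members of each list with the smallest p. Genes named outside the rule are marked in the text as chosen after their values were seen. Replication histone genes and Hist2h2aa1 belong to families of near-identical copies, so their assignment to a copy is uncertain.

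The alternatives fixed in advance were size factors by the RLE method, DESeq2 1.42.0, no filter on low counts, each library left out in turn, the replicate number or passage as a block, all 16 libraries in the diet fits, a purity covariate, genes enriched in IP only, each diet alone for IP against INPUT, only the 6 libraries of both groups in cEND cells, camera with an estimated correlation and fry. After the data were seen, further alternatives were added, namely ribosomal, mitochondrial and small structural RNA features left out before scaling, DESeq2 with the passage as a block and the block without each passage. The labels give the passage of each cEND library, and deviations from the group means correlated across genes within all 9 pairs of libraries of the same passage (Pearson r from 0.378 to 0.577 across genes, which are not independent replicates). The passage was therefore also fitted as a block, and the blocked counts stand beside the others. The main edgeR fit of each comparison, without a block, was tested on simulated data with known changes. Fits with a block, DESeq2 and camera were not tested in that way. In a further check chosen after the data were seen, the mean log2 CPM of each list was compared between diets with an exact permutation test over the 35 splits of 8 libraries, adjusted over 76 tests. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.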

Results

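The data cover 16 bacTRAP libraries of mouse hypothalamus in 4 groups of 4 pools (CD INPUT, CD IP, HFD INPUT and HFD IP) and 9 libraries of cEND cells in 3 groups of 3 passages (DMSO, WZB117 at 0.5 µM and WZB117 at 10 µM). Mean total counts were 36.2 ± 5.57 M in CD INPUT, 32.3 ± 5.98 M in CD IP, 35.7 ± 5.19 M in HFD INPUT and 33.6 ± 4.93 M in HFD IP (SD, n = 4 pools each). In cEND cells they were 33.3 ± 6.39 M with DMSO, 35.1 ± 6.25 M at 0.5 µM and 37.5 ± 2.72 M at 10 µM (SD, n = 3 passages each). Ribosomal RNA took 34.8 ± 1.05 percent of the counts in CD INPUT and 33.1 ± 2.67 percent in HFD INPUT. In the precipitated RNA it took 9.63 ± 0.298 percent in CD IP and 8.76 ± 1.18 percent in HFD IP. All features encoded in mitochondria, ribosomal RNA included, took 33.9 ± 0.67 percent in CD INPUT and 0.068 ± 0.008 percent in CD IP. Mitochondrial ribosomal RNA counts in both shares, so they overlap and cannot be added. The mitochondrial ribosomal RNA mt-Rnr2 alone took 20.5 to 21.7 percent of the CD INPUT libraries. The first principal component of the bacTRAP libraries held 80.8 percent of the variance and parted IP from INPUT. The first component of the cEND libraries held 31.7 percent and followed the passage.

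IP was compared with INPUT to see which transcripts the tagged ribosomes carried, since the study describes the Slco1c1 promoter as active in vascular endothelial cells of the blood-brain barrier. Slco1c1 itself (ENSMUSG00000030235, chromosome 6, 141524368 to 141570177), a transporter of thyroid hormone, rose from 11.3 ± 1.72 CPM in CD INPUT to 99.1 ± 13.9 CPM in CD IP (SD, n = 4 pools each). The log2 fold change was 3.12 ± 0.11 (SE) over both diets, with an adjusted p of 2.28e-13. Nrarp, a Notch-induced gene that dampens Notch signalling, rose by 4.79 ± 0.08 on the log2 scale, from 4.46 ± 0.809 to 127 ± 4.44 CPM in the CD pools. S1pr1, a receptor for sphingosine 1-phosphate, rose from 41.8 ± 5.69 to 479 ± 28.04 CPM. Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983), which encodes Glut1, rose from 30.7 ± 2.83 to 136 ± 13.8 CPM (log2 fold change 1.98 ± 0.07). The endothelial genes Cldn5, a tight junction component, and Pecam1, an adhesion molecule, rose by 2.24 ± 0.19 and 2.33 ± 0.10 on the log2 scale but reached only 3.40 ± 0.941 and 7.99 ± 0.843 CPM in CD IP.

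Astrocyte genes were among the transcripts most enriched in IP. All 10 measured members of the astrocyte list rose, with a median log2 fold change of 2.97 (camera adjusted p = 2.32e-19, adjusted p = 0.00213 with an estimated correlation). Among them Sox9, a glial transcription factor, went from 56.6 ± 1.78 to 475 ± 27.4 CPM in the CD pools. All 18 pan-endothelial genes rose as well, with a median of 2.15 (adjusted p = 0.000109, adjusted p = 0.248 with an estimated correlation). In the same way 24 of 27 blood-brain barrier genes rose while 2 fell (median 1.94, adjusted p = 3.93e-06, adjusted p = 0.248 with an estimated correlation). Shares were taken of the counts that remained after ribosomal, mitochondrial and structural RNA were set aside. The 10 astrocyte genes went from 0.424 ± 0.041 percent in CD INPUT to 2.50 ± 0.12 percent in CD IP. The 18 pan-endothelial genes went from 0.00485 ± 2e-04 to 0.0191 ± 0.0037 percent. The transcripts with the largest shares in IP were Ndrg2 with 2.82 ± 0.26 percent, Slc1a2, the main glutamate transporter of astrocytes, with 1.70 ± 0.20 percent, Sparc with 0.873 ± 0.096 percent and Aldoc, an aldolase, with 0.836 ± 0.058 percent (SD, n = 8 IP libraries, chosen after their values were seen). Heyl, Hey2, Hes1 and Hey1 were among 10 of 15 Notch target genes that rose, while 2 fell (median 2.14, adjusted p = 5.41e-05, adjusted p = 0.0297 with an estimated correlation). Further, 17 of 25 genes of Notch receptors, ligands and processing rose while 5 fell (median 0.64, adjusted p = 0.035, adjusted p = 0.334 with an estimated correlation). Notch1 rose by 2.39 ± 0.09 on the log2 scale, from 10.8 ± 1.11 to 61.2 ± 10.0 CPM in the CD pools. Of 24 genes of fatty acid uptake and oxidation, 22 rose and 2 fell (median 1.92, adjusted p = 5.45e-16, adjusted p = 0.0242 with an estimated correlation). An example is Cpt1a, the carnitine transferase of the outer mitochondrial membrane, which rose from 17.1 ± 0.682 to 104 ± 6.30 CPM.

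**Figure D1:**
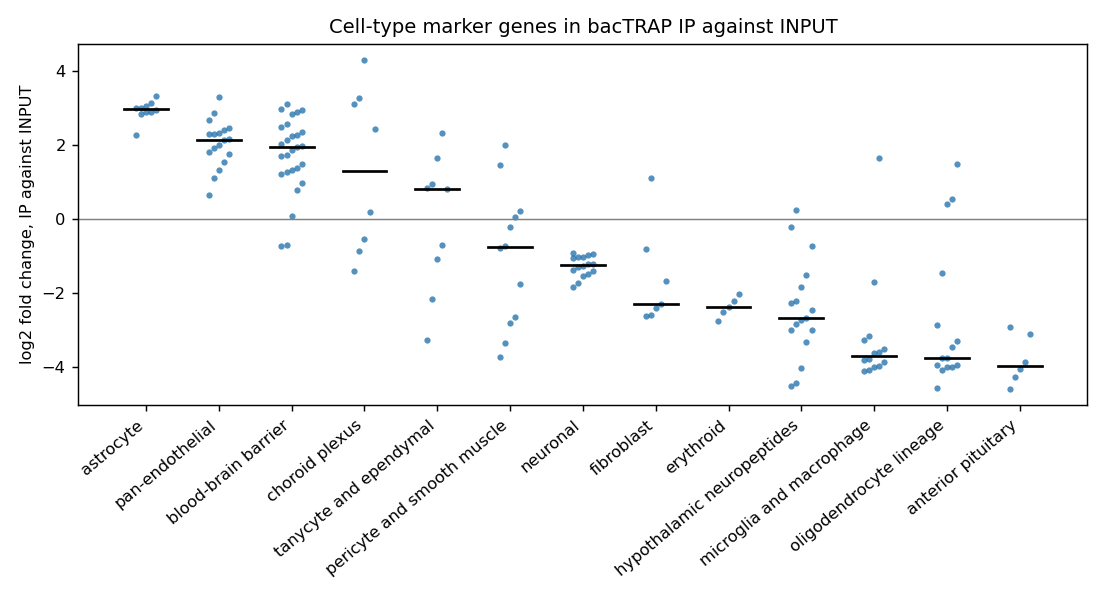
Each point is the log2 fold change of a marker gene in IP against INPUT over both diets (y axis, no unit) and each line is the median of its cell-type list (x axis). The median was 2.97 for the astrocyte list, 2.15 for the pan-endothelial list, -1.25 for the neuronal list and -3.75 for the oligodendrocyte list.

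Transcripts of neurons, oligodendrocytes and microglia fell in IP, as did those encoded in mitochondria. All 16 neuronal genes fell, with a median log2 fold change of -1.25 (adjusted p = 5.65e-09, adjusted p = 0.0557 with an estimated correlation). Likewise 16 of 17 neuropeptide genes fell (median -2.67, adjusted p = 6.49e-05, adjusted p = 0.0676 with an estimated correlation). Hcrt, the orexin precursor, went from 48.8 ± 7.78 to 2.52 ± 0.585 CPM in the CD pools. Of 15 oligodendrocyte genes 12 fell and 3 rose (median -3.75, adjusted p = 1.13e-14, adjusted p = 0.0113 with an estimated correlation). Mbp, a myelin protein, went from 957 ± 61.3 to 98.9 ± 9.21 CPM. Of 14 microglia and macrophage genes 13 fell and 1 rose (median -3.71, adjusted p = 2.06e-12, adjusted p = 0.049 with an estimated correlation). The 13 mitochondrially encoded genes fell (median -7.81, adjusted p = 2.61e-21, adjusted p = 0.0278 with an estimated correlation). The 5 erythroid genes fell too (median -2.38, adjusted p = 0.0341, adjusted p = 0.334 with an estimated correlation). Every measured gene of the anterior pituitary list, 6 in number, fell. Among other markers 6 of 7 fibroblast genes, 7 of 12 pericyte and smooth muscle genes, 4 of 9 tanycyte and ependymal genes and 2 of 8 choroid plexus genes fell, while 1, 2, 4 and 4 genes of the last 4 lists rose. None of these 5 lists passed camera (adjusted p from 0.381 to 0.739). The choroid plexus marker Ttr rose in IP by 4.29 ± 0.45 on the log2 scale.

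In all, 14724 of 17592 tested genes differed between IP and INPUT, 7315 upwards and 7409 downwards. Of these, 2991 rose and 3807 fell at least 2-fold. The camera test called 23 of 38 lists, of which 7 were called with an estimated correlation. Besides the lists given above these included, upwards, interferon response (22 of 23 genes rose, median 1.67), fatty acid synthesis (10 of 12, 1.66), Wnt and beta-catenin (12 of 14, 1.59), glucocorticoid response (11 of 16, 1.45) and VEGF and angiogenesis (13 of 16, 1.14). They further included the circadian clock (13 of 15, 0.73), NRF2 targets (13 of 16, 0.60), nuclear oxidative phosphorylation (39 of 41, 0.60), the amino acid and integrated stress response (11 of 21, 0.58) and glucose transport and glycolysis (20 of 23, 0.45). Ribosomal protein genes were called downwards (54 of 75 fell, median -0.27). Of these 11 lists, the clock alone was called with an estimated correlation (adjusted p = 0.049, against 0.0676 to 0.824 for the others). The lists for hypoxia, p53 targets, cholesterol synthesis, insulin signalling, endothelial activation, cell cycle, the unfolded protein response, immediate early genes, heat shock and extracellular matrix were not called (adjusted p from 0.141 to 0.899).

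HFD was compared with CD in the IP libraries to ask, as the study did, how 3 days of HFD alter the transcripts of the cells with tagged ribosomes. S100a11 (ENSMUSG00000027907, chromosome 3, 93520488 to 93526287), a calcium-binding protein, rose from 40.8 ± 7.49 CPM with CD to 74.3 ± 8.18 CPM with HFD (SD, n = 4 pools each). Its log2 fold change was 0.86 ± 0.12 (SE, adjusted p = 0.0305). The other named genes that rose included Hist2h2aa1, a histone, by 0.82 ± 0.14, and Ighm, the heavy chain of immunoglobulin M, by 0.68 ± 0.10 from 10.8 ± 1.32 to 17.3 ± 1.496 CPM. Upp1, a uridine phosphorylase, rose by 0.59 ± 0.10, and the non-coding RNA AW112010 rose by 0.53 ± 0.10. Agt (ENSMUSG00000031980, chromosome 8, 124556534 to 124569706), which encodes angiotensinogen and belongs to the astrocyte list, fell from 323 ± 32.2 to 222 ± 28.8 CPM. Its log2 fold change was -0.54 ± 0.09 (adjusted p = 0.0321). The cytochrome P450 gene Cyp2d22 fell by 0.53 ± 0.09 on the log2 scale and the cold-inducible RNA-binding protein gene Rbm3 by 0.47 ± 0.08. Prodh, which starts proline breakdown, fell by 0.46 ± 0.08, the ectonucleotidase gene Entpd2 by 0.45 ± 0.08 and Rin2, a regulator of endocytosis, by 0.39 ± 0.07. In total 14 of 15858 tested genes changed, 6 upwards and 8 downwards. Of these, 3 were outside the naming rule (Hist1h2ap, Gm16170 and Gm3005, chosen after their values were seen). In all 1831 genes had an unadjusted p under 0.05. The sex-linked genes Xist, Ddx3y, Kdm5d, Uty and Eif2s3y, fixed in advance as a check of the pools, were not among the 14. Scaled over all 16 bacTRAP libraries, Ddx3y stood at 30.2 to 36.8 CPM in CD IP. In HFD IP it stood at 24.7 to 26.9 CPM, without overlap. Kdm5d, Uty, Eif2s3y and Xist overlapped between the diets in IP. A smaller share of male RNA in the HFD pools was not tested and cannot be told apart from diet. DESeq2 gave 200 genes and leaving out the filter on low counts gave 398. Fitting all 16 bacTRAP libraries together gave 121 and testing only genes enriched in IP gave 29. The count was 33 without CD IP pool 1, 8 without CD IP pool 3 and 5 without CD IP pool 4. It was 6 without HFD IP pool 1, 50 without HFD IP pool 2, 9 without HFD IP pool 3 and 8 without HFD IP pool 4. The balance of directions shifted too, with 8 upwards and 25 downwards without CD IP pool 1, 8 and 1 without HFD IP pool 3, 46 and 75 with all 16 libraries and 8 and 21 among genes enriched in IP.

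**Figure D2:**
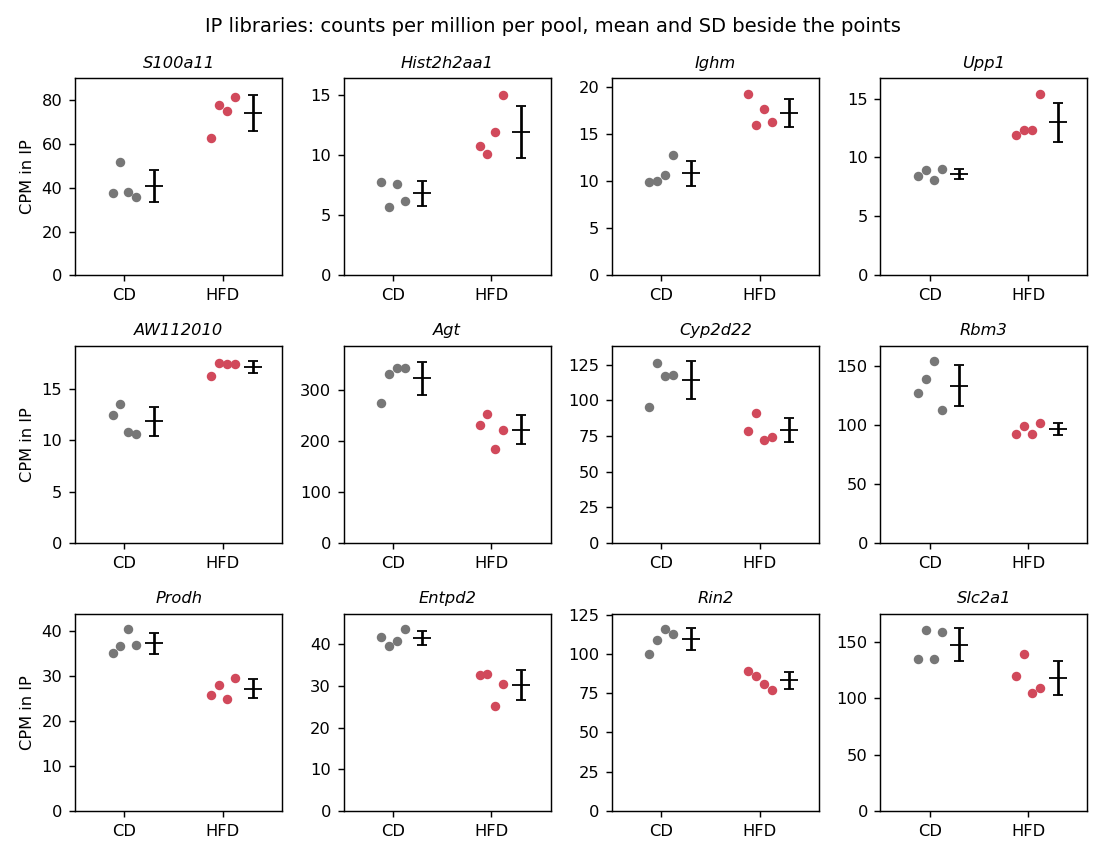
CPM (y axis, linear from 0) of the 11 genes named with HFD and of Slc2a1 in each of 4 CD and 4 HFD IP pools (x axis), with the mean and SD drawn beside the points. S100a11 went from 40.8 to 74.3 CPM and Agt from 323 to 222 CPM, and Slc2a1 stood at 147 and 118 CPM with an adjusted p of 0.161.

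The genes at the centre of the study's question did not pass the test in IP. With either diet the astrocyte list took a far larger share of the IP counts than the pan-endothelial list. The values of Slc2a1, Insr and the Notch genes therefore cannot be assigned to endothelial cells alone. A diet effect confined to endothelial cells could be missed here. Slc2a1 stood at 147 ± 14.6 CPM with CD and 118 ± 14.99 CPM with HFD (log2 fold change -0.32 ± 0.09, adjusted p = 0.161). Insr, the insulin receptor gene, stood at 54.8 ± 2.83 and 45.6 ± 2.18 CPM (-0.27 ± 0.07, adjusted p = 0.126). Notch1 stood at 66.1 ± 10.5 and 56.2 ± 7.90 CPM (-0.23 ± 0.12, adjusted p = 0.499). The Notch target genes Hes1, Hey1, Hey2 and Nrarp had log2 fold changes of -0.02 ± 0.10, 0.11 ± 0.08, -0.0088 ± 0.08 and 0.0042 ± 0.07, with adjusted p from 0.616 to 0.987. Values for Notch4, Dll4 and Jag1 were 0.13 ± 0.15, 0.38 ± 0.42 and -0.034 ± 0.16. Those for Slco1c1, Cldn5, Pecam1 and Vegfa were -0.19 ± 0.12, -0.016 ± 0.20, 0.069 ± 0.11 and 0.027 ± 0.10. Txnip, a gene that glucose induces, stood at 19.0 ± 3.45 and 12.3 ± 3.07 CPM (-0.62 ± 0.19, adjusted p = 0.246). Among list tests, neither the Notch target genes (0 of 15 past the test, median 0.035, camera adjusted p = 0.281) nor the genes of Notch receptors, ligands and processing (0 of 25, median -0.051, adjusted p = 0.0931) nor glucose transport and glycolysis (0 of 22, median -0.016, adjusted p = 0.554, with 1 up and 1 down adjusted over the list alone) were called. The insulin signalling list was called downwards (0 of 17 past the test, 3 down adjusted over the list alone, median -0.059, adjusted p = 0.0185, adjusted p = 0.578 with an estimated correlation).

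With HFD in IP, lists of the glucocorticoid response, the clock and lipid synthesis leaned downwards and ribosomal protein and interferon genes upwards, by the preset correlation only. Of 16 glucocorticoid-response genes 14 had a negative log2 fold change and 9 fell adjusted over the list alone (0 over all genes). The median was -0.35 (camera adjusted p = 4.6e-10, adjusted p = 0.578 with an estimated correlation). Members of the list were Plin4, a lipid droplet protein, at -1.30 ± 0.29 (1.90 ± 0.657 and 0.774 ± 0.230 CPM), the transcription factor gene Zbtb16 at -0.61 ± 0.15 and Fkbp5, a chaperone of the glucocorticoid receptor, at -0.44 ± 0.13. CD IP pool 1 had a mean log2 CPM of 4.90 over this list, against 5.32 to 5.34 in the other CD pools. Of 15 clock genes 13 were negative and 6 fell adjusted over the list alone (median -0.14, adjusted p = 7.21e-06, adjusted p = 0.15 with an estimated correlation). Dbp, a clock output gene, stood at 180 ± 14.2 and 150.0 ± 12.8 CPM. Per1 belongs to both lists. Ribosomal protein genes were positive in 74 of 75 cases and 15 rose adjusted over the list alone (median 0.16, adjusted p = 2.42e-23, adjusted p = 0.593 with an estimated correlation). All 23 interferon-response genes were positive, with none past the test (median 0.20, adjusted p = 8.38e-08, adjusted p = 0.635 with an estimated correlation).

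Further lists called in IP were fatty acid synthesis (10 of 12 negative, 2 down adjusted over the list alone, median -0.17, adjusted p = 0.000222) and cholesterol synthesis (21 of 21 negative, -0.14, 0.00499). Others were Wnt and beta-catenin (13 of 14 negative, -0.14, 0.00499), blood-brain barrier (20 of 27 negative, -0.096, 0.00788) and astrocyte (7 of 10 negative, 1 down over all genes, -0.099, 0.0174). Neuronal (13 of 16 negative, -0.081, 0.0185) and oligodendrocyte genes (10 of 15 negative, -0.29, 0.0185) were called downwards as well. Cell cycle genes (14 of 18 positive, median 0.35, adjusted p = 0.00359) and nuclear oxidative phosphorylation genes (33 of 41 positive, 0.053, 0.0185) were called upwards. With an estimated correlation their adjusted p ranged from 0.593 to 0.729, and none of the 14 lists called in IP was called. The pan-endothelial list was not called (0 of 18 past the test, median -0.075, adjusted p = 0.554). CD IP pool 3 had the lowest mean log2 CPM of that list, 2.24 against 2.73 to 2.81 in the other CD pools. The same pool was low for blood-brain barrier genes (3.5 against 3.92 to 4). HFD IP pool 2 was high for Wnt and beta-catenin genes (4.16 against 3.82 to 3.85 in the other HFD pools). In the exact permutation test of list means, the clock list differed by -0.16 between diets in IP (p = 0.0286, the smallest that 35 splits allow, with all 4 HFD pools below all 4 CD pools). In the same exact test the glucocorticoid-response list differed by -0.39 (p = 0.0571), both with an adjusted p of 0.271.

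**Figure D3:**
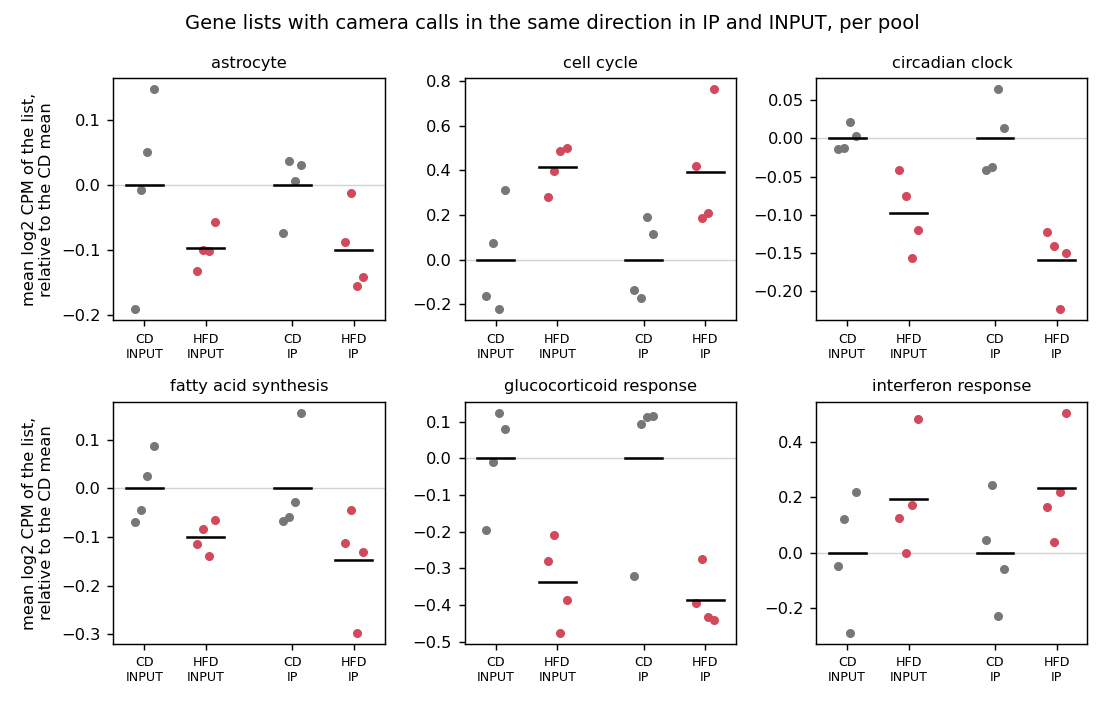
Mean log2 CPM of 6 gene lists in each bacTRAP pool (points), relative to the CD mean of the same fraction (y axis), for INPUT and IP with CD (grey) or HFD (red), with lines at the group means. The glucocorticoid-response mean was lower by 0.386 in HFD IP and by 0.338 in HFD INPUT, which the exact test gave an adjusted p of 0.271 each.

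The same diet comparison in INPUT gives the background of the whole hypothalamus. Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880) fell from 87.8 ± 11.4 to 52.7 ± 4.30 CPM (SD, n = 4 pools each). Its log2 fold change was -0.74 ± 0.09 (adjusted p = 0.00981). Cirbp, a related cold-inducible RNA-binding protein gene, fell from 18.6 ± 1.03 to 12.9 ± 1.49 CPM (-0.51 ± 0.08). Vim, which encodes the intermediate filament vimentin, rose from 15.4 ± 1.04 to 23.4 ± 1.94 CPM (0.60 ± 0.08, adjusted p = 0.0056). Ifitm2, an interferon-induced membrane protein gene, rose from 5.70 ± 0.272 to 8.65 ± 0.563 CPM. S100a11 rose from 10.7 ± 1.22 to 15.9 ± 1.08 CPM and the tubulin gene Tubb2b from 68.2 ± 3.15 to 86.2 ± 5.17 CPM. These 6 of 16879 tested genes were all that changed, while 1258 had an unadjusted p under 0.05. Slc2a1, Insr, Notch1, Hes1, Nrarp and Txnip had log2 fold changes of 0.0054 ± 0.08, -0.031 ± 0.05, -0.048 ± 0.10, 0.074 ± 0.20, 0.056 ± 0.16 and 0.0045 ± 0.11, with adjusted p from 0.933 to 0.995. DESeq2 gave 52 genes, leaving out the filter on low counts 116 and fitting all 16 libraries together 2. The count was 2 without CD INPUT pool 3, 12 without CD INPUT pool 4, 17 without HFD INPUT pool 2 (7 upwards and 10 downwards) and 2 without HFD INPUT pool 4.

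In INPUT 13 lists were called. Glucocorticoid-response genes were negative in 15 of 16 cases. Adjusted over the list alone, 6 fell and 1 rose (median -0.28, adjusted p = 8.25e-10, adjusted p = 0.24 with an estimated correlation). Plin4 stood at 2.39 ± 0.545 and 0.843 ± 0.351 CPM. Clock genes were negative in 12 of 15 cases (median -0.11, 0.000468), as were 10 of 12 genes of fatty acid synthesis (-0.11, 0.000859) and 7 of 10 astrocyte genes (-0.096, 0.0037). Positive values prevailed for interferon response (21 of 23, median 0.19, 7.16e-08), cell cycle (22 of 25, 0.30, 2.11e-07), and pan-endothelial genes (13 of 16, 0.33, 7.75e-06). The same held for heat shock (12 of 13, 0.11, 0.000359), immediate early (17 of 20, 0.12, 0.0037), endothelial activation and inflammation (11 of 12, 0.19, 0.0039) and extracellular matrix genes (16 of 19, 0.13, 0.0189). Ribosomal protein genes (56 of 75 negative, median -0.044, 0.00749) and nuclear oxidative phosphorylation genes (31 of 41 negative, -0.045, 0.00786) were called downwards. With an estimated correlation none of the 13 was called (adjusted p from 0.24 to 0.921). The anterior pituitary list took 0.153 percent of the counts of CD INPUT pool 1, against 0.00507 to 0.00789 percent in the other CD INPUT pools. Its share varied among the HFD INPUT pools too, from 0.00131 to 0.0326 percent. In the exact permutation test the list means differed by -0.34 for glucocorticoid response and by -0.098 for the clock (p = 0.0286 each, adjusted p = 0.271). The adjusted p decides as little here as in IP. In the same exact test 3 further lists, all higher with HFD, had the same p of 0.0286 and adjusted p of 0.271, pan-endothelial at 0.31, heat shock at 0.18 and the amino acid and integrated stress response at 0.044.

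The interaction test asked whether the diet effect differed between IP and INPUT, which the study's focus on the tagged cells makes the relevant contrast. No gene of 17592 passed in edgeR, with 755 at an unadjusted p under 0.05, and DESeq2 gave 4. The smallest p belonged to Upp1 (ENSMUSG00000020407, chromosome 11, 9118103 to 9136170), with 7.98 ± 0.412 and 11.9 ± 1.45 CPM in CD and HFD IP against 1.24 ± 0.0664 and 0.907 ± 0.112 CPM in CD and HFD INPUT (difference of log2 fold changes 1.03 ± 0.19, adjusted p = 0.206). The next by p were Arrdc3 at 0.44 ± 0.10, Art3, 4930563E18Rik and Gm3005, with adjusted p of 0.865 each. The differences were -0.34 ± 0.14 for Slc2a1, -0.25 ± 0.08 for Insr and -0.20 ± 0.17 for Notch1 (adjusted p of 1.00 each). Leaving out CD INPUT pool 2, or CD IP pool 1, 3 or 4, gave 1 gene each. Camera called 11 lists on the difference. Ribosomal protein genes (74 of 75 positive, median 0.19) and nuclear oxidative phosphorylation genes (36 of 41 positive, 0.10) were called upwards. Pan-endothelial (15 of 18 negative, -0.41), blood-brain barrier (24 of 27 negative, -0.15) and insulin signalling genes (14 of 17 negative, -0.088) were among the 9 called downwards. The pan-endothelial difference came mainly from higher values with HFD in INPUT (median 0.33, against -0.075 in IP). With an estimated correlation none of the 11 was called (adjusted p from 0.634 to 0.764). Neither Notch list was called (adjusted p of 0.0748 and 0.746). Across 15373 genes tested in both fractions the diet effects had a Pearson r of 0.287, across genes that are not independent replicates. INPUT and IP libraries of the same diet and number also varied together in 7 of 8 cases, so no shared effect of diet was read from this r.

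The study used WZB117 in cEND cells to ask whether Notch signalling responds to lowered glucose transport. At 0.5 µM no gene of 15466 passed in edgeR against DMSO, and DESeq2 gave 0 as well. An unadjusted p under 0.05 was found for 55 genes (0.356 percent), far fewer than that threshold gives without any effect. The fit without the block keeps differences between passages in its spread and was conservative here, so its 0 is weak evidence of no effect. With the passage as a block the count was also 0, with 219 at an unadjusted p under 0.05. The 5 genes of smallest p, Gm15899, Gm22107, Gm10702, Otoa and Gm43750, all had an average log2 CPM under 0. Slc2a1 stood at 84.7 ± 14.4 CPM with DMSO and 84.9 ± 17.6 CPM at 0.5 µM (SD, n = 3 passages each), Notch1 at 266 ± 40.8 and 265 ± 12.7 CPM and Hes1 at 36.7 ± 7.65 and 37.8 ± 9.90 CPM. In simulated data with the same groups, fitted without the block, 17.9 percent of 1.5-fold, 55.2 percent of 2-fold and 78.8 percent of 4-fold changes were recovered. The simulated libraries held no passage effects, so these shares need not hold for the real ones. Without the block the mitochondrially encoded list was the only one of the tested lists called (11 of 13 negative, median -0.14, adjusted p = 0.0468, adjusted p = 0.975 with an estimated correlation). With the passage as a block 6 lists were called, among them Notch receptors, ligands and processing upwards (0 of 23 genes past the test, adjusted p = 0.0151, adjusted p = 0.711 with an estimated correlation). The pan-endothelial list was called upwards too with the block (0 of 18, adjusted p = 0.0369, adjusted p = 0.711 with an estimated correlation).

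At 10 µM genes of the hypoxia response rose. Bnip3 (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519), a mitophagy receptor induced by hypoxia, rose from 21.1 ± 6.68 CPM with DMSO to 191 ± 19.1 CPM (SD, n = 3 passages each). Its log2 fold change was 3.18 ± 0.29 (SE, adjusted p = 0.00245). Eno2, an enolase, rose from 5.45 ± 0.275 to 36.3 ± 7.57 CPM (2.73 ± 0.16). Adm, the gene of the vasodilator adrenomedullin, rose from 9.72 ± 2.89 to 52.2 ± 11.7 CPM (2.42 ± 0.32). Slc2a1, the gene of the inhibitor's own target, rose from 84.7 ± 14.4 to 320 ± 50.8 CPM (1.92 ± 0.19, adjusted p = 0.00309). Vegfa, the vascular endothelial growth factor gene, rose from 32.6 ± 4.25 to 78.3 ± 5.00 CPM (1.26 ± 0.12). The other named genes that rose were Smtnl2, Ankrd37, Ndrg1, Selenbp1, Ccng2, a cyclin linked to growth arrest, Mxi1, an antagonist of Myc, and Unc13a, with log2 fold changes from 1.99 to 2.59. All 10 genes named downwards were replication histone genes of chromosome 13, whose copies are hard to tell apart. They ran from Hist1h1a at -2.61 ± 0.43 (11.2 ± 2.91 to 1.83 ± 0.900 CPM) to Hist1h3a at -1.57 ± 0.23.

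**Figure D4:**
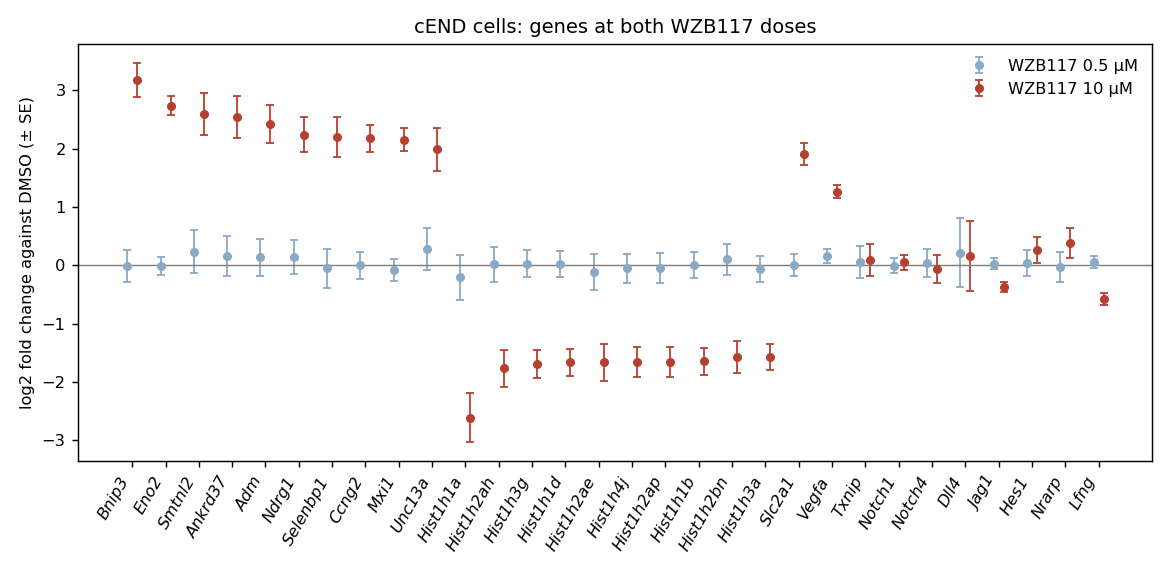
Log2 fold change against DMSO (y axis, points with SE, n = 3 passages per group) of the 20 genes named at 10 µM and of genes of glucose sensing and Notch signalling (x axis), at WZB117 0.5 µM (blue) and 10 µM (red). Bnip3 stood at 3.18 at 10 µM and at -0.0096 at 0.5 µM, Hist1h1a at -2.61 and -0.21.

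In total 197 of 15466 genes changed at 10 µM, 132 upwards and 65 downwards, 113 of them at least 2-fold, and DESeq2 gave 534. With the passage as a block 2864 genes changed, 1427 upwards and 1437 downwards. Of the 197, 194 were among them. Without the block, the count was 38 without DMSO passage 12 (34 upwards and 4 downwards), 61 without DMSO passage 14 (51 and 10) and 112 without DMSO passage 18 (73 and 39). It was 42 without passage 12 at 10 µM (37 and 5) and 103 without passage 18 at 10 µM (88 and 15). Of 18 hypoxia-response genes 12 rose, 17 adjusted over the list alone and 17 with the block (median 1.27, camera adjusted p = 3.37e-71, adjusted p = 0.00575 with an estimated correlation). Of 16 genes of the unfolded protein response 9 rose, 16 adjusted over the list alone (median 0.54, adjusted p = 0.0311 with an estimated correlation). The chaperone gene Hspa5 rose from 908 ± 51.2 to 1480.0 ± 43.1 CPM and Dnajb9 by 1.37 ± 0.15 on the log2 scale. Of 21 genes of glucose transport and glycolysis 6 rose, 14 adjusted over the list alone (median 0.53, adjusted p = 0.0377 with an estimated correlation). The phosphofructokinase gene Pfkl rose from 252 ± 54.8 to 574 ± 39.0 CPM and the hexokinase gene Hk1 from 271 ± 22.7 to 450.1 ± 25.1 CPM. Slc2a1 and other genes belong to both the hypoxia and the glycolysis list. Of 16 NRF2 targets 3 rose, 9 adjusted over the list alone (median 0.36, adjusted p = 0.0311 with an estimated correlation). Hmox1, the heme oxygenase gene, rose by 1.25 ± 0.18 on the log2 scale. Of 16 immediate early genes 2 rose, Nr4a2 and Fos, and 8 adjusted over the list alone (median 0.69, adjusted p = 0.0311 with an estimated correlation). With both the block and an estimated correlation none of these 5 lists was called (adjusted p from 0.165 to 0.289).

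**Figure D5:**
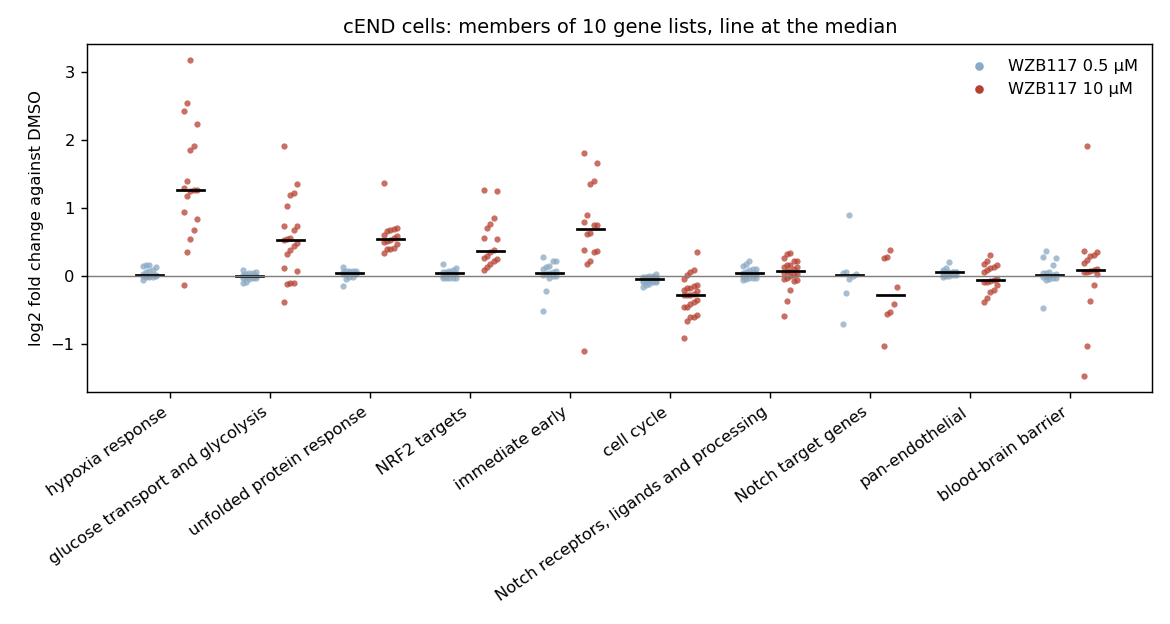
Log2 fold change against DMSO (y axis) of each member of 10 gene lists (x axis) at WZB117 0.5 µM (blue) and 10 µM (red), with lines at the medians. At 10 µM the median was 1.27 for the hypoxia response, 0.54 for the unfolded protein response, 0.078 for Notch receptors, ligands and processing and -0.053 for pan-endothelial genes.

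Neither Notch list was called at 10 µM, and the number of Notch genes past the test depended on the block on passage. Without the block Lfng, a glycosyltransferase that modifies Notch receptors, fell from 28.9 ± 1.82 to 19.3 ± 1.28 CPM (-0.58 ± 0.10, adjusted p = 0.0291). It was the only member of the 23 genes of Notch receptors, ligands and processing past the test, with 2 down adjusted over the list alone (median 0.078, camera adjusted p = 0.832). The Notch target genes had 0 of 8 past the test (median -0.28, adjusted p = 0.9). Jag1, a Notch ligand, stood at 140 ± 14.6 and 108 ± 2.93 CPM (-0.37 ± 0.09, adjusted p = 0.112), and Notch1 at 266 ± 40.8 and 275 ± 31.4 CPM. Hes1 and Nrarp had log2 fold changes of 0.26 ± 0.22 and 0.38 ± 0.26 (adjusted p of 0.792 and 0.699). With the passage as a block 4 genes of the receptor list rose and 2 fell, and 3 target genes rose and 1 fell. Blocked adjusted p were 0.000149 for Jag1, 0.00992 for Hes1 and 0.00413 for Nrarp. Neither list was called with the block (adjusted p of 0.515 and 0.819). Insr had a log2 fold change of 0.23 ± 0.19, Cldn5 of 0.24 ± 0.40 and Pecam1 of 0.16 ± 0.17. Notch4 had -0.060 ± 0.23, Dll4 0.16 ± 0.59 and Txnip 0.091 ± 0.27, and none of these passed the test.

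Of the remaining lists at 10 µM, camera called the amino acid and integrated stress response (21 of 23 positive, median 0.31, adjusted p = 2.57e-06), glucocorticoid response (1 of 9 up, Cdkn1a, 0.48, 6.24e-06) and p53 targets (1 of 15 up, again Cdkn1a, 0.22, 0.000803) upwards. It also called cholesterol synthesis (18 of 21 positive, 0.17, 0.00268) and fatty acid uptake and oxidation (17 of 23 positive, 0.090, 0.0265) upwards, and the cell cycle downwards (21 of 25 negative, -0.27, 9.97e-06). None of these 6 was called with an estimated correlation (adjusted p from 0.067 to 0.624). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose from 11.8 ± 1.72 to 44.8 ± 10.3 CPM, and Plk1, a mitotic kinase, stood at 56.3 ± 11.8 and 30.0 ± 5.82 CPM (adjusted p = 0.133, and 1.68e-08 with the block). With the block 14 of 25 cell cycle genes fell and 12 of 23 genes of the amino acid and integrated stress response rose. The pan-endothelial, blood-brain barrier, insulin signalling, endothelial activation and interferon lists were not called (adjusted p from 0.129 to 0.998). With the block heat shock was called upwards (adjusted p = 0.0434, adjusted p = 0.68 with an estimated correlation) and the interferon list downwards (10 of 23 fell and 1 rose, adjusted p = 0.00076, adjusted p = 0.687 with an estimated correlation).

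The doses were compared directly to see whether 10 µM differed from 0.5 µM. Of 15466 genes 197 changed, 133 upwards and 64 downwards. DESeq2 gave 524 and the block on passage gave 2759, 1436 upwards and 1323 downwards. Slc2a1 was higher at 10 µM by 1.91 ± 0.19 on the log2 scale (320 ± 50.8 against 84.9 ± 17.6 CPM) and Bnip3 by 3.19 ± 0.29 (191 ± 19.1 against 21.0 ± 7.36 CPM). Camera called 10 lists, all of them also called at 10 µM against DMSO, and 5 stayed with an estimated correlation, among them hypoxia response with 12 of 18 genes up (adjusted p = 0.00601 with an estimated correlation). The remaining 4 were the unfolded protein response with 8 of 16, glucose transport and glycolysis with 6 of 21, NRF2 targets with 3 of 16 and immediate early genes with 1 of 16 (adjusted p = 0.0355 each with an estimated correlation). The other 5, the amino acid and integrated stress response, glucocorticoid response, p53 targets, fatty acid uptake and oxidation and the cell cycle, had adjusted p from 0.116 to 0.798 with an estimated correlation. With both the block and an estimated correlation none of the first 5 was called (adjusted p from 0.178 to 0.346). With the block alone fatty acid uptake and oxidation lost its call (adjusted p = 0.0741), and heat shock and insulin signalling were called upwards and interferon response downwards (adjusted p of 0.0363, 0.0305 and 0.000428, adjusted p = 0.648 each with an estimated correlation). Without the block, the count was 34 without passage 12 at 0.5 µM (28 upwards and 6 downwards) and 54 without passage 14 at 0.5 µM (46 and 8). It was 33 without passage 12 at 10 µM (30 and 3), 92 without passage 18 at 10 µM (79 and 13) and 79 when only the 6 libraries of both groups were fitted (62 and 17). Across 15458 genes the fold changes of both doses against DMSO had a Pearson r of 0.326. Both share the DMSO libraries, and simple differences of group means gave an r of 0.309 and a covariance of 0.028. Simulated unchanged groups that shared their controls gave an r of 0.511 and a covariance of 0.0348 ± 0.00237 (SD, 100 simulations). The simulated groups kept the spread left after the passage was taken out, and their values lay above the observed ones, so no shared effect of the doses was read from them. Across 12496 genes the effect of HFD in IP and that of WZB117 had an r of -0.0969 at 10 µM and -0.0147 at 0.5 µM. Of the genes called at 10 µM, 70 of 177 that were tested in IP had the same sign with HFD.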

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

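The tests in this part were chosen after each pattern was seen, apart from the splits of the libraries by gene counts in the last paragraph, which were fixed before the data were examined. Among 256 groups of 4 libraries tested with Dixon's rule (critical value 0.829), 15 had a library far from the others, where chance alone marks about 5 percent.

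Library CD IP 2 had 41.2 M counts, against 28.5 to 29.8 M in the other CD IP libraries, and 52 CPM of S100a11, against 35.7 to 37.9 CPM. Upp1 stood at 15.4 CPM in HFD IP 4 (11.9 to 12.3 in the others) and AW112010 at 16.3 CPM in HFD IP 1 (17.4 to 17.5 in the others). Notch4 stood at 3.29 CPM in CD IP 3 (4.5 to 4.55) and at 5.87 CPM in HFD IP 2 (4.08 to 4.36), and Ddx3y at 29.9 CPM in HFD INPUT 2 (25.2 to 26). In list means of log2 CPM, CD IP 3 had 3.5 for blood-brain barrier genes (3.92 to 4) and 2.24 for pan-endothelial genes (2.73 to 2.81), CD IP 1 had 4.9 for glucocorticoid-response genes (5.32 to 5.34) and HFD IP 2 had 4.16 for Wnt and beta-catenin genes (3.82 to 3.85). In shares of counts, fibroblast genes took 0.00451 percent in CD IP 4 (0.00104 to 0.00157) and neuropeptide genes 0.0494 percent in HFD INPUT 2 (0.0617 to 0.0642). Anterior pituitary genes took 0.153 percent in CD INPUT 1 (0.00507 to 0.00789) and 0.00854 percent in CD IP 1 (0.000316 to 0.000464).

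Lists whose diet effect differed between IP and INPUT by camera were ribosomal proteins (adjusted p = 1.36e-30) and nuclear oxidative phosphorylation (8.48e-05) upwards. Upwards means a diet effect in IP above that in INPUT. Downwards were pan-endothelial (2.65e-05), blood-brain barrier (0.000954), oligodendrocyte (0.00209), cholesterol synthesis (0.00493), neuronal and insulin signalling (0.00818 each), Wnt and beta-catenin (0.00986), extracellular matrix (0.0445) and microglia genes (0.0483). A call downwards is not by itself a fall in IP. The pan-endothelial list had a median of -0.075 with HFD in IP and of 0.33 in INPUT. None was called with an estimated correlation.

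Astrocyte genes stood above INPUT in the IP libraries. Carryover of unbound hypothalamic RNA would bring IP closer to INPUT and would not by itself lift genes above INPUT. The fall of the neuronal genes (median log2 fold change -1.25, SD 0.278 over 16 genes) is therefore no separate test of carryover. Ribosomal and mitochondrial RNA taking counts in INPUT would shift all other genes by a single factor, yet the astrocyte median lay 4.22 above the neuronal one (SD 0.274 over the 10 astrocyte genes), which argues against it as the cause of that gap. All 10 astrocyte genes lay above INPUT (median log2 fold change 2.97), which argues against carryover alone as the cause for these genes. Astrocyte transcripts were thus enriched by the precipitation. Expression of the tag in astrocytes was not measured, and no precipitation without the tag was among the libraries.

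The glucocorticoid-response list leaned lower with HFD in both fractions by the preset correlation only, with adjusted p of 0.578 in IP and 0.24 in INPUT with an estimated correlation. Collection at another time of day would move clock genes of opposite phase in opposite directions, and in INPUT the Bmal1-phase genes had a median of 0.0753 (median SE 0.0958) against -0.139 (median SE 0.0764) for the Dbp and Per phase, so the Bmal1-phase value lay within its SE. In IP the medians were 0.121 (median SE 0.0811) and -0.261 (median SE 0.0752), opposite and each beyond its SE, as another collection time predicts. The Bmal1-phase genes were split, with Arntl at 0.313, Nfil3 at 0.242 and Clock at 0.121 but Npas2 at -0.0604 and Cry1 at -0.138. Each SE is typical of a single gene and is not the SE of a median. Another collection time stays a candidate explanation, since sampling times are not in the labels. These values do not tell it apart from an effect of diet on the clock genes. Carryover of INPUT RNA into IP would give genes enriched at least 2-fold in IP a weaker change than in INPUT. The 9 such genes had a median of -0.281 in IP (median SE 0.136) and -0.264 in INPUT. With an SE of that size a weaker change in IP is not excluded, so carryover stays open. By list mean, 2 of 35 splits of the IP libraries gave a difference as large, so a grouping by chance remains possible there, and 1 of 35 did in INPUT.

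Hypoxia-response genes were higher with WZB117 at 10 µM. Each treatment was run once at each of the 3 passages, so passage was balanced between the groups. Lower glucose entry would be expected to lower Txnip and Arrdc4, targets of the glucose sensor MondoA. With the block Txnip had a log2 fold change of 0.112 (SE 0.066) and Arrdc4 0.159 (SE 0.14), so neither fell. These transcripts alone, at a treatment time that is not given, cannot decide whether less glucose entered the cells. Oxygen and glucose levels of the cultures were not analysed here.

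The libraries were also split in other ways of the same sizes, in all ways for each comparison but IP against INPUT, for which 40 splits were drawn, the real one included. Of these 40, 1, the real one, had as many genes (13923 in a fit of 2 groups, with 11555 as the highest other). For HFD in IP 1 of 35 splits had as many (14 genes, with 4 as the highest other), and for HFD in INPUT 2 of 35 did (6 genes, with 9 as the highest other), so a split by chance could give the INPUT count. For the difference of diet effects, with INPUT and IP libraries of the same diet and number moved together, all 35 of 35 splits had as many as the 0 observed. In cEND cells 10 of 10 splits had as many at 0.5 µM, and 1 of 10 at 10 µM and between doses, where 10 splits are too few for a share under 0.05. The highest other split gave 0 genes at 10 µM and between doses, against 197 each. With the passage as a block, 4 splits kept all 3 passages in each part, the real one included. There the real split gave 2864 genes at 10 µM and 2759 between doses, against 0 in the highest other, and 0 at 0.5 µM, against 2. These splits too are few for a share under 0.05.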

How the results depend on the processing

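The count for IP against INPUT stayed between 12920 (CD libraries alone) and 17239 (no filter on low counts). Lists called there went from 23 to 7 with an estimated correlation and to 36 with fry. Other counts depended on the setting, and the cause was not tested except where fewer genes or libraries entered. For HFD in IP the 14 genes became 200 with DESeq2, 398 without the filter on low counts, 121 with all 16 libraries in the fit, 29 among genes enriched in IP and 52 with the replicate number as a block. The balance of directions shifted from 6 up and 8 down to 33 up and 19 down with that block, 8 and 1 without HFD IP 3 and 8 and 25 without CD IP 1. For HFD in INPUT the 6 genes became 52 with DESeq2, 116 without the filter, 2 with all 16 libraries and 43 with the number as a block, under which Rbm3 had an adjusted p of 0.11. Those numbers are shared only as numbers, and deviations of CD and HFD libraries of the same number correlated with r from -0.0157 to 0.0709 across genes, which are not independent replicates, against -0.00655 to 0.136 for INPUT and IP libraries of the same diet and number. Whether those come from the same pool is not given in the labels, which share only the number. The difference of diet effects gave 0 genes, 4 with DESeq2, 1 without the filter and 1 with diet and number as a block. In all 3 of these comparisons 0 lists were called with an estimated correlation and 0 with fry.

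At 0.5 µM WZB117 0 genes were called in every setting, with 0 lists by an estimated correlation, 0 by fry and 6 with the passage as a block. Those were mitochondrially encoded and cell cycle genes downwards, and Notch receptors, ligands and processing, cholesterol synthesis, pan-endothelial and oligodendrocyte genes upwards. With both the block and an estimated correlation none was called (adjusted p from 0.711 to 0.934). At 10 µM against DMSO the 197 genes became 534 with DESeq2, 2864 with the block, 2673 with DESeq2 and the block, and 1628, 2412 and 1998 with the block without passage 12, 14 or 18. Lists went from 11 to 5 with an estimated correlation and 7 with fry. At 10 against 0.5 µM the 197 genes became 524 with DESeq2, 2759 with the block, 2556 with DESeq2 and the block, 1493, 2285 and 2049 with the block without passage 12, 14 or 18, and 79 with 6 libraries. Lists went from 10 to 5 with an estimated correlation and 6 with fry. The DESeq2 fits with the block and the fits without a passage were chosen after seeing the data. With single libraries left out, counts ran from 14665 to 14874 for IP against INPUT, from 5 to 50 for HFD in IP, from 2 to 17 for HFD in INPUT, from 0 to 1 for the difference of diet effects, from 38 to 171 at 10 µM and from 33 to 152 between doses. Simulated changes of 1.5-fold were recovered in 67.2 percent of cases for HFD in IP and 8.96 percent at 10 µM. In such data smaller changes in cEND cells are largely out of reach without the block. The simulation held no passage effects, so its shares need not hold for the real cEND libraries. False calls occurred as well. For HFD in IP 16 unchanged genes were called, beside 45, 50 and 62 genes changed 1.5-fold, 2-fold and 4-fold. At 0.5 µM 10 unchanged genes were called, beside 12, 37 and 52 changed ones in the same order.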

Other observations

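The tests of S-phase genes below were chosen after the result was seen, and the test of T and NK cell genes was written before its values were. Genes induced by interferon gamma, chosen after their values were seen, were measured in the bacTRAP libraries of both diets. CPM in this paragraph were scaled by total counts alone, without TMM factors, so their ratios differ from the fitted fold changes. Cxcl9, a T cell chemokine, stood at 59.9 ± 17 CPM in INPUT and 73 ± 20 CPM in IP (fitted log2 fold change 0.060, adjusted p = 0.625 in edgeR). Cxcl10 stood at 45 ± 14 and 272 ± 74 CPM (2.36), the immunity-related GTPase Iigp1 at 74.2 ± 8.8 and 436 ± 45 CPM (2.31) and the class I light chain B2m at 654 ± 76 and 2460 ± 260 CPM (1.67; SD, n = 8 libraries each). Of 14 genes of T and NK cells, 7 reached 1 CPM in the mean of INPUT and 1 stayed under 0.2 CPM. Cd3e stood at 1.90 ± 0.48 CPM and Cd8a at 2.60 ± 0.78 CPM. These values leave some T or NK cells in the samples possible, but the 7 include Trac, which was enriched in IP. Erythroid transcripts were found in INPUT too, and cells of blood left in the vessels were not told apart from cells of the tissue. In IP 11 of the 12 measured fell, while Trac rose by 2.41 on the log2 scale, with 4.65 ± 0.78 CPM in INPUT and 29.3 ± 5.1 CPM in IP.

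The 10 genes named downwards with WZB117 at 10 µM were replication histone genes. Fewer cells in S phase could lower them. With the passage as a block their log2 fold changes ran from -2.65 to -1.56 (median -1.63), while the 19 S-phase genes had a median of -0.208 (SD 0.182). The S-phase genes thus fell far less than the histone genes. How much each set falls with fewer S-phase cells was not measured, so these values do not decide whether that was the whole cause. Of the 19, 5 fell with the block and 0 without it (median -0.172). Of 25 cell cycle genes 14 fell and 0 rose with the block. Whether fewer S-phase cells made a part or the whole of the change stays open.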
